A study of Homo sapiens with 18 samples.

How the data were processed

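Small RNA of WPMY-1 cells, an immortalised human prostate stromal myofibroblast line, was measured by m1A-MAP-seq. N1-methyladenosine (m1A) is a methylated adenosine that stops or misleads reverse transcriptase, so that cDNAs end next to it or carry a mismatch at it. Per the labels' protocols, RNA was immunoprecipitated with an m1A antibody, and the immunoprecipitated (IP) RNA was split into a part treated with the demethylase AlkB and an untreated part; input RNA was sequenced beside them. The cells carried an empty vector or an shRNA against TRMT61A, the catalytic subunit of the methyltransferase that makes m1A at position 58 of cytosolic tRNAs. Of the 18 libraries, 3 belonged to each of 6 groups, taken from the labels: input, AlkB-untreated IP and AlkB-treated IP of vector and of knockdown cells. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

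The table lists 725 adenosine sites in 180 tRNA genes. Per the file headers, the authors deposited for each library the count of reads that cover the site and the count of those with a mismatch, not normalised. The deposited mismatch rate is a fraction, the quotient of both counts, and every cell matched that quotient within 1e-09. The authors' difference column equals the untreated minus the treated rate of a replicate with negative values set to 0, and their fold column is the ratio of both rates, set to 1000 where only the treated rate is 0; both were recomputed without a deviation. Per the submitters' processing notes, cutadapt 1.9.3, Bowtie2 2.2.4, SAMtools 1.3.1 and the build hg38 were used; their parameters and the rule by which sites were listed are not given in the sources used here. A further 19 lines of the table are not analysed here, nor is the TRMT61A mRNA, so the knockdown itself was not checked. Site counts end near 8000 reads, with a highest value of 8015, which caps the depth of the best covered sites in the IP libraries and with it their read-through and anticodon counts. Reads of near-identical tRNA genes appeared to be shared out among the copies, so values of single genes of an isodecoder family are uncertain and not independent. Which base was read at a mismatch is not analysed here. Coordinates are those of the table (hg38), printed 1-based. Of the 180 genes, 172 had a RefSeq tRNA gene at the same coordinates. 6 lines whose counts repeated another line in all 18 libraries were counted once. Replicates of a group differed by more than counting noise in every pair, with a chi-square per degree of freedom from 1.73 to 571.

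Sites were classed before the data were examined by the nucleotide number in the gene: numbers 8 to 10 as position 9, 13 to 15 as position 14, and 54 to 75 as T-loop where the adenosine followed TTC and 1 further base. This gave 83 T-loop, 16 position-9, 61 position-14 and 565 other sites. All 83 T-loop sites lie 15 nucleotides before the 3′ end, which is position 58; a further 8 sites at that distance, in intron-containing or unusual genes, fell into the class of other positions. No mitochondrial tRNA was listed. The design had foreseen files with or without read counts. Since counts were there, each site with at least 20 reads in every library of a comparison was tested with a quasi-binomial logistic model of mismatched over total reads in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05, two-sided. Treated and untreated parts of the same IP, and IP and input of the same number, were compared with the replicate number as a block, since the protocol splits them from the same RNA. The effect of knockdown on the AlkB-sensitive part was tested with limma 3.58.1 on the difference of the logit of untreated and treated rates (offset 0.01). Medians per library were compared by two-sided exact permutation tests, which cannot go below p = 0.1 with 3 against 3 libraries. In no pair of groups did all same-numbered libraries correlate above 0.1 in their deviations; between the untreated and treated vector libraries the lowest correlation was 0.06 for mismatch rates and -0.24 for reads.

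Sites were named by a rule fixed before the data were examined: those past the threshold in each comparison; in the AlkB-untreated knockdown comparison also up to 6 per direction by smallest unadjusted p; the T-loop site with the highest vector level of each amino acid, among sites with at least 20 reads in each library of that comparison; and up to 12 position-9 sites. A21 of valine tRNAs and A34 of arginine tRNAs were chosen after their values were seen.

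3 measures of coverage were added after the data were examined. Read-through of position 58 is the number of reads at the site 15 nucleotides before the 3′ end over the median number at sites 0 to 8 nucleotides from that end, for the 66 tRNAs with both. It was summed per library and, for tRNAs with at least 20 reads at the 3′ end in each library, tested per tRNA with limma on log2 of the ratio (pseudocount 0.5). The step between neighbouring adenosines is the number of reads at one over the number at its neighbour toward the 3′ end. Both measures are quotients of counts at different sites and can exceed 100%. Summed quotients depend on the mix of tRNAs, so they were also computed with each tRNA weighted by its mean share of the denominator reads in vector, for tRNAs with at least 20 such reads in each library. The reads of each tRNA at its best covered site were summed by anticodon and tested with edgeR 4.0.16 (quasi-likelihood, TMM scaling), with DESeq2 1.42.0 as an alternative. The mapped total of each library is not given in the sources used here, so anticodon changes are relative to the other listed tRNAs. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

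The tests were tested on simulated data drawn from the real depths and rates. Simulated libraries of a group shared the same rate at each site or tRNA, with counting error only. Anticodon counts had a small fixed dispersion. Where real replicates spread more, the recovered shares below are best-case values. In the AlkB-untreated knockdown comparison, 76.9% of sites set from 10% to 5% were recovered over 255 sites, and 66.7% of 4-fold rises from the real rates, which are far lower. These simulations also called 49 of 2050 unchanged sites, and 0 when the dispersion was held at 1 or more. The blocked comparisons had little power: 17.7% of sites set from 10% to 2.5% were recovered in each of the AlkB comparisons in vector (293 sites) and knockdown (271 sites) and in the IP comparison (270 sites). In the input comparison (428 sites) 10 simulations without any change gave 29 calls in all, and 0 when the dispersion was held at 1 or more. For read-through per tRNA, 81.7% of 2-fold changes were recovered over 52 tRNAs, and for anticodon coverage 95% over 45 anticodons. Intervals are exact 95% binomial intervals; they and the limits from a count of 0, set at 3 counts, cover counting error only, since reads carried no molecular identifiers. Alternatives were another scale, offset, filter, read minimum, block, tool or unit of testing, and leaving out each library in turn.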

Results

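The study asked how loss of TRMT61A alters m1A in small RNA of WPMY-1 prostate stromal cells. Mismatch counts were available at 725 adenosines of 180 tRNA genes in 18 libraries, 3 for each of 6 groups: input, AlkB-untreated IP and AlkB-treated IP RNA of vector and TRMT61A-knockdown cells. Reads summed over sites ranged from 225301 to 307981 in the input libraries and from 115580 to 890428 in the IP libraries. At this depth the vector IP libraries without AlkB had 353 to 477 sites with at least 20 reads, and the corresponding knockdown libraries 394 to 503.

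The median mismatch rate at the T-loop adenosine, position 58 of the tRNA, the site methylated by TRMT6/TRMT61A, was below 1% in both lines. With reads pooled over 25 T-loop sites, input had 0.55% ± 0.17 in vector and 0.65% ± 0.19 in knockdown (SD, n = 3, exact permutation p = 0.6). The AlkB-untreated IP had 0.66% ± 0.036 and 0.59% ± 0.064 over 39 sites (SD, n = 3). The sets of sites differ, but the IP rates lay close to those in input. In the AlkB-untreated IP libraries the median over 39 T-loop sites was 0.632% ± 0.0682 (SD, n = 3) in vector and 0.501% ± 0.13 (SD, n = 3) in knockdown cells. These libraries overlapped, and the difference of -0.131 percentage points did not pass an exact permutation test (p = 0.3, adjusted p = 0.45 over 3 site classes). It was -0.0554 without knockdown replicate 2 and -0.0628 with reads pooled over sites. The mean over these sites, in contrast to the median, did not overlap, at 0.7% to 0.955% in vector and 0.546% to 0.582% in knockdown libraries. An exact permutation test of 3 against 3 libraries cannot go below p = 0.1. Of the 39 T-loop sites, 25 had a lower and 14 a higher mean after knockdown. For each of 10 amino acids the T-loop site with the highest vector level was followed, a choice that by itself favours a lower mean after knockdown. Among them was Val-CAC-2-1 A58 (chromosome 6, 27280270 to 27280342), with 2.63% ± 2.35 (SD, n = 3) in vector, from 2 mismatched of 73 reads, and 0 of 108 reads in knockdown, which allows up to 2.78%. Gln-CTG-4-1 A57 (chromosome 1, 148265108 to 148265179) had 1.68% ± 1.65 in vector and 0.236% ± 0.409 in knockdown (SD, n = 3), with as few as 84 reads in a vector library; with reads pooled it had 0.671% and 0.595%. Arg-ACG-2-1 A58 (chromosome 3, 45688999 to 45689071) had 0.909% ± 0.339 and 0.289% ± 0.0599 (SD, n = 3), at 570 to 3508 reads per library. Pro-AGG-1-1 A57 had 1.07% ± 0.598 and 0.561% ± 0.627, and Ser-AGA-2-6 A67 had 1.09% ± 0.81 and 0.534% ± 0.499 (SD, n = 3). Leu-CAG-1-1 A68, the deepest of them, had 0.722% ± 0.048 and 0.63% ± 0.0786 (SD, n = 3). Thr-TGT-6-1 A57 had 1.05% ± 0.507 in vector and 1.06% ± 0.252 in knockdown (SD, n = 3). No T-loop site passed the quasi-binomial test, also when adjusted over the list alone; 3 had an unadjusted p under 0.05, and limma called 0 of all sites.

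**Figure D1:**
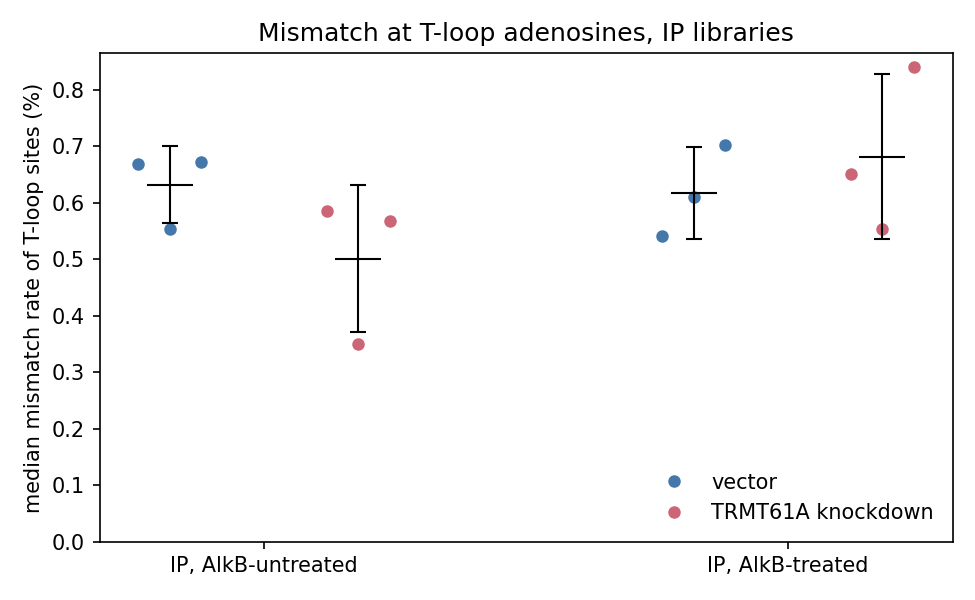
Median mismatch rate over T-loop adenosines (percent) in each IP library without (39 sites) and with (51 sites) AlkB treatment, with vector in blue and TRMT61A knockdown in red; points are libraries and bars show the mean and SD. The knockdown libraries without AlkB have a mean of 0.501% against 0.632% in vector and overlap with them.

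Among amino acids, the T-loop median was lower after knockdown in 9 of 10. Valine (7 sites) had 0.785% ± 0.466 in vector and 0.298% ± 0.258 in knockdown, and serine (7 sites) had 0.812% ± 0.0934 and 0.413% ± 0.358 (SD, n = 3). These 2 did not overlap between groups, against 1 of 10 given by chance at a share of 10%, and their exact permutation p of 0.1 became 0.5 after adjustment. With reads pooled over sites, valine had 0.634% and 0.614% and serine 0.728% and 0.753%, so serine turned. Leucine alone had a higher T-loop median, 0.599% ± 0.0797 in vector and 0.636% ± 0.112 in knockdown (SD, n = 3).

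Over all positions, no site passed in the AlkB-untreated knockdown comparison. The quasi-binomial test called 0 of 255 sites (lowest adjusted p = 0.154), limma also 0, and 21 sites had an unadjusted p under 0.05 where 12.8 arise by chance. Of those 21, 7 were lower and 14 higher in knockdown. The excess over 12.8 depends on the model: 3 sites had such a p with the dispersion held at 1 or more, and 9 with limma. The lower sites with the smallest p lay in the acceptor stem of Ala-TGC-3-2 (A66, 0.244% in vector and 0.0707% in knockdown) and in Val-CAC-2-1 (A70, A67 and A58), with Phe-GAA-1-3 A58 (0.4% and 0.0976%) and Gly-CCC-1-1 A20 (0.0999% and 0.0622%). The higher ones were Ser-AGA-4-1 A77 (0 of 1407 vector reads and 0.149% in knockdown), Val-TAC-1-1 A73, Val-TAC-2-1 A70 and A73, Gly-CCC-2-2 A71 and Val-CAC-3-1 A71 (0.166% and 0.863%). None of these 12 passed the adjustment, and several rest on few mismatched reads. Val-TAC-1-1 A73 and Val-TAC-2-1 A73 had 1 in all knockdown libraries, Val-TAC-2-1 A70 had 2 and Ser-AGA-4-1 A77 had 3, against 0 in vector. Val-CAC-2-1 A70 and A67 had 6 and 12 of 2979 vector reads and 0 of 147 knockdown reads, which allows up to 2.04%. Leaving out knockdown replicate 2 of these libraries gave 1 call.

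The median over all 255 sites was 0.272% ± 0.0277 in vector and 0.244% ± 0.0746 in knockdown (SD, n = 3), with an exact permutation p of 0.8; without knockdown replicate 2 the difference turned to 0.0166 percentage points. Position-14 sites (12 sites) had 0.224% ± 0.0614 and 0.288% ± 0.00813 (SD, n = 3), without overlap, an exact permutation p of 0.1 and an adjusted p of 0.3. Sites at other positions (204) had 0.209% ± 0.0361 and 0.189% ± 0.0477 (SD, n = 3; exact permutation p = 0.6). Position 9, methylated in mitochondrial tRNAs by another enzyme, was listed only for nuclear tRNAs of alanine, lysine, valine and others. None of its sites had 20 reads in all libraries of this comparison. In vector the 12 highest ran from 0.0439% at Val-CAC-2-1 A9 to 0.522% at Ala-TGC-4-1 A9 and 1.2% at Lys-CTT-2-1 A9, the last with 1 to 194 reads per library.

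AlkB, which removes the methyl group, left the mismatch rates of tRNA sites without a detected change in vector cells. T-loop sites had a median of 0.618% ± 0.0813 in the AlkB-treated vector libraries (51 sites; SD, n = 3), against the 0.632% without AlkB given above. The latter is a median over 39 sites, so the sets of sites differ. The blocked quasi-binomial test called 0 of 251 sites in vector, with 8 at an unadjusted p under 0.05; limma called 0. This test has little power: 17.7% of simulated falls from 10% to 2.5% were recovered. Val-AAC-5-1 A21 had 19.7% without and 25.6% with AlkB, and Gln-CTG-2-1 A57 had 0.461% and 0.917%; neither passed. In the authors' deposited table, the difference of untreated minus treated rates was above 0 at 680 of the 725 sites in at least 1 replicate and at 4 sites in all 6. Among sites with at least 20 reads in both parts, it was above 0 at 31.9% to 53.1% of sites over the 6 replicates. In 4 of the 6 replicates more sites lay below 0 before flooring than above, as in knockdown replicate 1 with 207 below and 163 above.

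In knockdown cells AlkB treatment raised 1 of 249 sites. Leu-CAA-4-1 A92 (chromosome 1, 248873855 to 248873960), which lies 14 nucleotides before the 3′ end of this leucine tRNA, had 0.531% ± 0.118 without and 1.29% ± 0.296 with AlkB (SD, n = 3). Its adjusted p in the quasi-binomial model was 0.0391, and no site passed without the block or in limma. The T-loop sites Ala-TGC-3-2 A57 (0.772% and 0.947%) and Arg-ACG-2-1 A58 (0.289% and 0.575%) were also higher with AlkB, without overlap and without passing (adjusted p in the same model 0.149 and 0.316). Knockdown changed the AlkB-sensitive part of the mismatch at 0 of 228 sites by limma, with 8 at an unadjusted p under 0.05, 6 of them lower; no other tool was run.

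Within the AlkB-treated libraries, knockdown changed 0 of 359 sites by the quasi-binomial test (lowest adjusted p = 0.0752), limma called 0, and 31 had an unadjusted p under 0.05. The T-loop median there was 0.618% ± 0.0813 in vector and 0.682% ± 0.146 in knockdown (SD, n = 3; exact permutation p = 0.6). The site nearest the threshold was Leu-CAA-3-1 A107 at the 3′ end, listed at 0 in vector and at 0.232% in knockdown. Leaving out knockdown replicate 3 gave 2 calls, and leaving out vector replicate 1 gave 1.

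Compared with input, the vector IP had lower mismatch rates at A21 of the valine tRNAs Val-AAC and Val-CAC, without passing the test. Val-AAC-1-1 A21 (chromosome 3, 169772230 to 169772302) had 39.7% ± 3.29 in input and 21.4% ± 1.82 in the IP (SD, n = 3), with 399 to 898 reads per IP library and an adjusted p of 0.0607 in the blocked quasi-binomial model. Val-AAC-5-1 A21 had 40.9% and 19.7%, and Val-CAC-4-1 A21 had 39.1% and 21.6%. Pooled over 8 such genes, which share reads, A21 mismatched in 41.1% ± 0.982 of vector input and 22.5% ± 3.61 of vector IP reads (SD, n = 3; exact permutation p = 0.1, the smallest this design allows). After knockdown the same sites had 34.9% ± 6.78 in input and 33.6% ± 4.36 in the AlkB-untreated IP (SD, n = 3), where replicate 1 had only 7 reads and the others 1985 and 1735. A24 of the same genes had 1.35% as many reads as A21 and mismatched in 34.3% of them, and A9 in 7 of these genes mismatched in 0.0751% of reads. In this comparison 0 of 202 sites passed, limma called 0, and 14 had an unadjusted p under 0.05, 13 of them lower in the IP. Limma on untransformed rates called 4 sites, all lower, and the fit without the block called 2, both higher.

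In input RNA, mismatch rates at single sites differed little between vector and knockdown. Of 379 sites, 2 passed in the quasi-binomial model, where 35 had an unadjusted p under 0.05, and limma called the same 2. Leu-CAA-2-1 A93 (chromosome 6, 27605638 to 27605745), which is position 58 of this intron-containing leucine tRNA gene, mismatched in 1.06% ± 0.113 of vector input reads (SD, n = 3) and in 0 of 165 knockdown reads, which allows up to 1.82%. Cys-GCA-2-2 A22 (chromosome 17, 38867645 to 38867716) mismatched in 0 of 494 vector reads, which allows up to 0.607%, and in 0.628% ± 0.0858 of knockdown reads (SD, n = 3). Both had an adjusted p of 0.00548 in that model and rest on 3 mismatched reads in all, 1 per library; neither passed with the dispersion held at 1 or more, where 0 sites did. Leaving out 1 library gave 0 to 8 calls: 0 without knockdown replicate 1, 7 without vector replicate 1, and 8 each without vector replicate 2 and knockdown replicate 3. Reads pooled over 428 sites mismatched at 0.683% ± 0.0135 in vector and 0.564% ± 0.0344 in knockdown input (SD, n = 3; exact permutation p = 0.1). Without A21 of Val-AAC and Val-CAC the pooled rates were 0.294% ± 0.019 and 0.302% ± 0.0117 (420 sites; SD, n = 3; exact permutation p = 0.5), and the medians over all sites were 0.158% and 0.153% (exact permutation p = 1).

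Input reads passed position 58 more often after knockdown. Summed over 66 tRNAs, the reads at position 58 were 10.6% ± 0.157 of those at the 3′ end in vector and 17.3% ± 0.934 in knockdown input (SD, n = 3), 1.63 times as many. The vector libraries lay between 10.4% and 10.8% and the knockdown libraries between 16.4% and 18.3%, and the exact permutation p was 0.1, the smallest 3 against 3 libraries allow. This difference was smaller when the mix of tRNAs was held. The mix is that of the 3′-end reads, so a change in 3′ fragments that differs between tRNAs would shift it too. With the mix of 52 tRNAs held at the vector mean, read-through was 10.6% ± 0.283 and 13.5% ± 0.702 (SD, n = 3; exact permutation p = 0.1), a difference of 2.91 percentage points against 6.55 for the summed reads of the same tRNAs. The median log2 change per tRNA was 0.44. These measures were chosen after the data were examined. Of 52 tRNAs with enough reads, 49 had a higher ratio after knockdown and 16 passed limma's test, all higher; 27 did not overlap between groups, all higher, where chance gives 5.2 at a share of 10%. In tyrosine tRNAs 5 of 6 passed, in glutamine tRNAs 5 of 7, in valine tRNAs 3 of 7, in leucine tRNAs 2 of 8 and in proline tRNAs 1 of 7. No alanine (0 of 7), glycine (0 of 3) or serine tRNA (0 of 4) passed by limma, and over all 52 tRNAs 19 had an unadjusted p under 0.05. A lack of calls can reflect depth. Ser-AGA-3-1, Ser-AGA-4-1 and Ser-TGA-2-1 had log2 changes of 1.02, 1.13 and 1.03 at 21 to 57 reads at the 3′ end per library. The remaining serine tRNA, Ser-TGA-4-1, had 0.09 at 263 to 380 reads, and the called Gln-TTG-2-1 had 765 to 1377 reads.

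The largest log2 change was that of Tyr-GTA-2-1 (chromosome 2, 27050782 to 27050870), with 1.88% in vector and 4.95% in knockdown, a log2 change of 1.43 with SE 0.17 (limma adjusted p = 0.00897). Gln-TTG-2-1 (chromosome 6, 28589379 to 28589450) had 7.61% and 12.8%, a log2 change of 0.74 with SE 0.09 (limma adjusted p = 0.00897). Val-AAC-1-1 had 0.867% and 1.6% (limma adjusted p = 0.0264), Gln-CTG-1-4 had 13.9% and 18.6% (limma adjusted p = 0.0295), and Leu-CAA-4-1 had 23.9% and 34.5% (limma adjusted p = 0.0431). With the mix within each amino acid held at the vector mean, glutamine tRNAs had 13.2% ± 0.549 in vector and 18.4% ± 0.747 in knockdown, tyrosine tRNAs 1.48% ± 0.211 and 2.97% ± 0.539, and serine tRNAs 30% ± 1.08 and 34.1% ± 0.997 (SD, n = 3). Valine tRNAs had 7.97% ± 0.0666 and 9.18% ± 0.0776 (SD, n = 3), whereas their summed reads gave 16.4% in knockdown. The initiator tRNA iMet had 92.9% ± 0.795 and 97.9% ± 0.839 (SD, n = 3). The count of calls rests on all 6 libraries: it was 1, 3 and 0 without vector replicates 1, 2 and 3, and 13, 5 and 0 without knockdown replicates 1, 2 and 3. With reads of each anticodon summed, 9 of 24 anticodons passed, and 23 were higher.

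**Figure D2:**
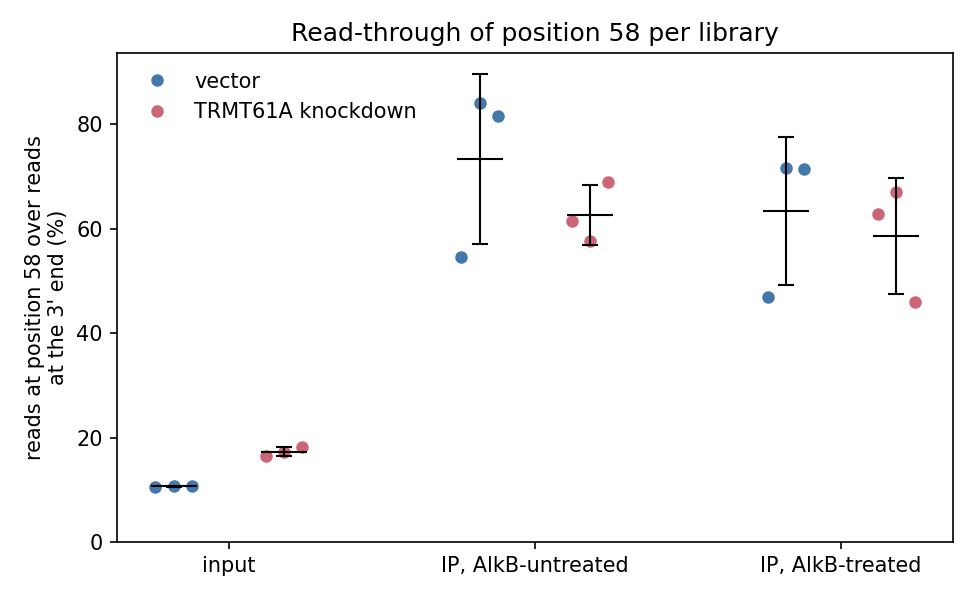
Reads at position 58 as percent of the reads at the 3′ end, summed over 66 tRNAs, in each input and IP library of vector (blue) and TRMT61A-knockdown cells (red); points are libraries and bars show the mean and SD. The input libraries have means of 10.6% and 17.3% and do not overlap, whereas the IP groups do; the mix of tRNAs is not held fixed.

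**Figure D3:**
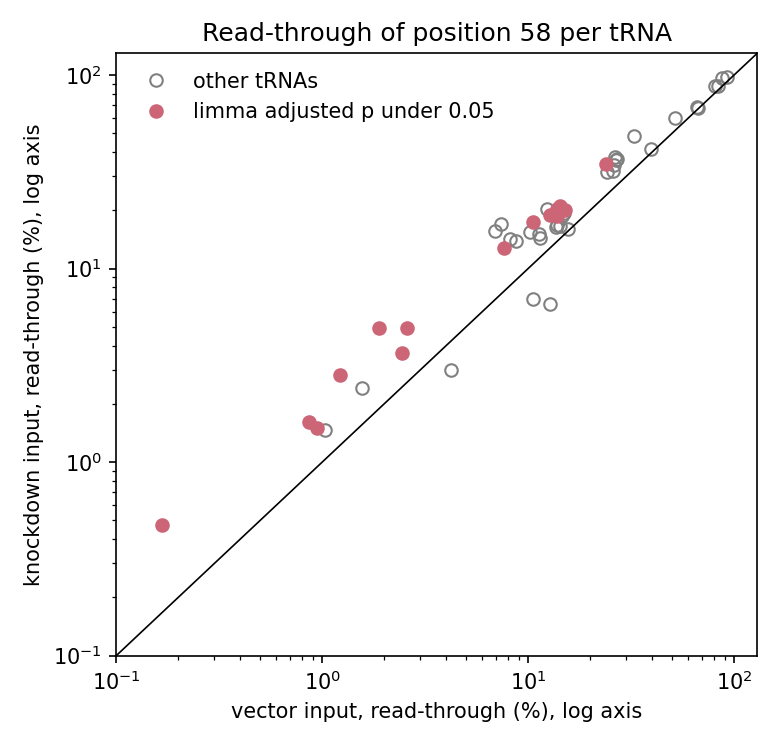
Read-through of position 58 for each of 52 tRNAs in input, vector on the horizontal and knockdown on the vertical axis (percent, log axes), with the 16 tRNAs past limma's adjusted threshold filled and the line of equality drawn. In all, 49 tRNAs lie above the line.

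The step into position 58 differed between vector and knockdown input, and its neighbours, read in fewer tRNAs, showed no difference. Reads at position 58 numbered 17.9% ± 0.558 of those at position 59 in vector and 25.1% ± 1.59 in knockdown (54 tRNAs; SD, n = 3; exact permutation p = 0.1), and 28 of the 32 tRNAs with enough reads were higher. With the mix of these 32 held at the vector mean it was 17.9% ± 1 and 23.1% ± 1.13 (SD, n = 3; exact permutation p = 0.1). Reads at position 59 numbered 32.2% ± 0.291 and 33.4% ± 1.55 of those at position 60 (5 tRNAs; SD, n = 3; exact permutation p = 0.4). Reads at position 57 numbered 79.4% ± 2.67 and 80.1% ± 1.84 of those at position 58 (31 tRNAs; SD, n = 3; exact permutation p = 0.7).

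**Figure D4:**
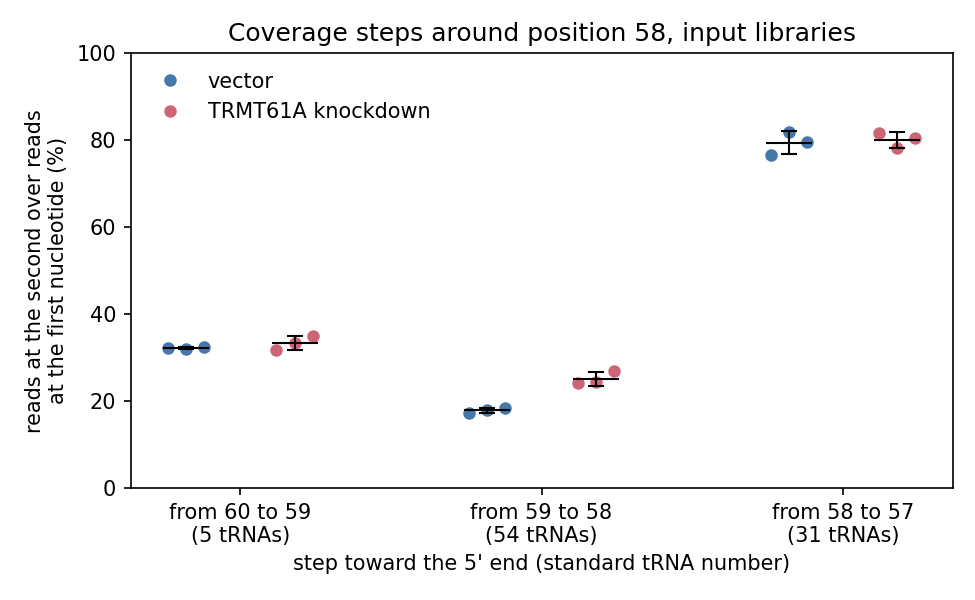
Reads at an adenosine as percent of those at its neighbour toward the 3′ end, at the steps from position 60 to 59, 59 to 58 and 58 to 57 in the input libraries, vector in blue and knockdown in red; points are libraries and bars show the mean and SD. Only at the step from 59 to 58 do the groups lie apart, at 17.9% and 25.1%.

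In the IP libraries reads passed position 58 far more often than in input. Read-through was 73.4% ± 16.4 in the vector IP without AlkB, 6.91 times the vector input, and 62.7% ± 5.76 in the knockdown IP, 3.62 times its input (SD, n = 3; exact permutation p = 0.1 for each). With the mix of tRNAs held at that of input it was 5.4 and 2.92 times the input, a log2 change of 2.43 and 1.55. Holding the mix at that of the IP gave smaller log2 changes, 1.75 in vector and 1.15 in knockdown. The cap on site depth limits the 3′-end reads of the best covered tRNAs in the IP but not in input. Without the 6 tRNAs near it, the values with the input mix held were 5.82 and 3.37 times the input. Summed over tRNAs, vector and knockdown IP libraries overlapped, both without AlkB (exact permutation p = 0.4) and with AlkB, where it was 63.4% ± 14.2 and 58.7% ± 11.1 (SD, n = 3; exact permutation p = 0.5). By limma 0 of 44 tRNAs passed in either, with 5 without AlkB and 0 with AlkB at an unadjusted p under 0.05. Those 5 were all tyrosine tRNAs without overlap between groups, where chance gives 4.4 of the 44 tRNAs. Of these, 4 with nearly the same read counts were higher in knockdown, as Tyr-GTA-2-1 with 3.71% and 47.7% and Tyr-GTA-5-4 with 3.87% and 45.7% (limma adjusted p = 0.0683 each). Tyr-GTA-8-1 was lower, with 85.1% and 3.9% (limma adjusted p = 0.276); these tRNAs had as few as 29 reads at the 3′ end in a library. Whether the effect of knockdown differs between input and IP was not tested.

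Coverage of anticodons in input also differed between vector and knockdown. Of 44 anticodons, 19 passed edgeR's test, 8 higher and 11 lower in knockdown. The glycine tRNAs Gly-GCC and Gly-CCC were higher, with log2 fold changes of 0.85 (SE 0.08, edgeR adjusted p = 3.58e-20) and 0.67 (SE 0.07, edgeR adjusted p = 4.61e-16), followed by Glu-TTC (0.50) and Lys-TTT (0.47). Leu-CAA was lower, with a log2 fold change of -0.88 (SE 0.09, edgeR adjusted p = 1.41e-18), as were elongator Met-CAT (-0.76), Val-AAC (-0.76), Tyr-GTA (-0.70), Val-CAC (-0.68), Leu-CAG (-0.65) and Gln-TTG (-0.44). The initiator iMet-CAT did not pass (-0.11, edgeR adjusted p = 0.491). These changes went with the part of the tRNA that was read: the 5 called anticodons with reads mainly toward the 5′ end were all higher, and of the 14 with reads mainly toward the 3′ end 11 were lower (Fisher's exact p = 0.00482). The ratio of reads in the 5′ part to reads in the 3′ part rose from 0.66 ± 0.0484 in vector to 1.32 ± 0.0822 in knockdown input (SD, n = 3; exact permutation p = 0.1). As a ratio of sums over tRNAs it also depends on their mix, which was not held fixed for it. In the IP libraries edgeR called 0 of 36 anticodons without AlkB and 0 of 43 with AlkB, with 0 and 4 at an unadjusted p under 0.05; DESeq2 was run on input only. Counts of the deepest anticodons, such as Gly-GCC, end at the depth cap in IP libraries, so the lack of calls there cannot be set against the 19 in input.

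**Figure D5:**
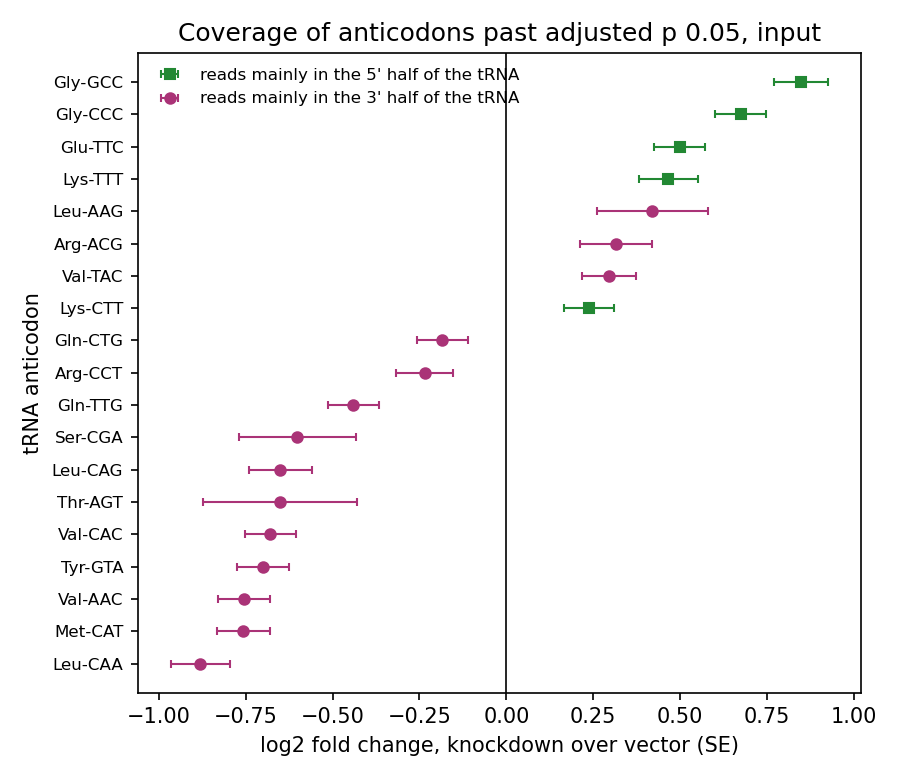
Log2 fold change of coverage, knockdown over vector, of the 19 anticodons past edgeR's adjusted threshold in input, with SE bars; green squares are anticodons read mainly toward the 5′ end of the tRNA and purple circles those read mainly toward the 3′ end. Gly-GCC is the highest at 0.85 and Leu-CAA the lowest at -0.88.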

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

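All tests in this part, the splits of the read-through and coverage results included, were chosen after the results were seen.

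At A34 of Arg-ACG-2-1 (chromosome 3, 45688999 to 45689071), the first anticodon base, 110 of 121 reads over the 12 IP libraries mismatched, 90.9% (exact 95% interval 84.3% to 95.4%), against 9 of 223 input reads, 4.04% (1.86% to 7.52%). At A34 of Arg-ACG-1-3 (chromosome 14, 22929701 to 22929773) it was 11 of 15 IP reads, 73.3% (44.9% to 92.2%), against 4 of 202 input reads, 1.98% (0.542% to 4.99%). Both sites were looked at because the IP signal lies above that in input. They miss the read minimum of every comparison with IP libraries, so no test of IP against input was made. Arg-ACG-1-3 A34 met it only between vector and knockdown input, where it did not pass (quasi-binomial adjusted p = 0.875). All 11 IP libraries with a read at the first site lay at 58.3% or above, and no input library there lay above 8.51%. Of its 121 IP reads, 67 came from 1 library, the AlkB-treated knockdown replicate 1. Most IP reads of this site came from AlkB-treated RNA. With AlkB, 15 of 16 vector and 77 of 86 knockdown reads mismatched there, and without AlkB 6 of 6 and 12 of 13. At Arg-ACG-1-3 the lowest IP library lay at 33.3% and the highest input library at 9.09%, with at most 3 reads in an IP library. The IP reads at A34 are few: A51 of Arg-ACG-2-1 had 62.6 times as many reads as A34 in the IP libraries and 1.52 times as many in input. The mismatch stayed high with AlkB, which m1A that AlkB had removed would not give. No T-loop site passed the AlkB tests either, so the action of AlkB at A34 cannot be judged. The counts do not identify the modification: m1A is not shown, and one other than m1A at A34 is not excluded.

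More input reads passed position 58 after TRMT61A knockdown. Holding the mix of tRNAs took 3.64 of 6.55 percentage points off the summed change with the vector mix and 3.3 with the knockdown mix. This mix is that of the 3′-end reads, the denominator of read-through. It can shift with 3′ fragments too, so that part is not assigned to a separate cause. A changed mix is argued against as the cause of all, since 49 of 52 single tRNAs had a higher ratio. A tilt of coverage close to position 58 is argued against by the neighbouring steps. The larger of these changed by a log2 of 0.05 (0.0501) against 0.49 at the step from 59 to 58, or 0.37 with the mix held. They rest on fewer tRNAs, 4 and 7 with at least 20 reads. A wider shift stays open, since reads 46 to 80 nucleotides from the 3′ end also rose. Summed over 40 tRNAs, with their mix not held, they were 0.67 to 0.72 times the 3′-end reads in vector and 1.59 to 1.72 times in knockdown input. Fewer stops of reverse transcriptase at a less methylated A58 may give the change at the step from 59 to 58 (0.491). Fewer 3′ tRNA fragments that begin just after position 58 would give it as well, and the counts cannot tell these apart. Nor was this step shown to measure m1A at A58, as stops at m1A alone would make it lower in the IP and higher with AlkB. In vector it was 17.9% ± 0.558 in input, 80.6% ± 5.43 in the untreated IP and 79.8% ± 3.16 with AlkB. In knockdown it was 25.1% ± 1.59, 76.1% ± 5.22 and 73.5% ± 12.5 (SD, n = 3, mix not held). In 10 splits of the 6 libraries only the real one, 1 of 10, gave as many calls, with 16 tRNAs against 0 in the highest other split; 10 splits are too few for a share under 0.05.

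The mismatch of about 31.3% at A21 of valine tRNAs, 14770 of 47239 reads in 8 genes, was seen in both input and IP. In vector, enrichment of the mismatched reads by the antibody is argued against, since the IP lay at -18.6 percentage points relative to input. This does not exclude m1A at A21, since the antibody also binds RNA with m1A at other positions. In knockdown the IP without AlkB and the input were close, at 33.6% and 34.9%, with 7 reads in an IP library. AlkB moved the pooled rate by 3.68 percentage points in vector (exact permutation p = 0.4) and by -7.58 in knockdown (exact permutation p = 0.6). Misread bases at the end of reads stay open: A24 had 1.35% as many reads as A21, so few reads go on past A21, but A24 itself mismatched in 218 of 636 reads, 34.3%. The counts do not tell where the mismatched reads end, and the base read is not analysed here. No biological explanation was tested.

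The coverage of 19 anticodons in input moved with knockdown, and the shift from 3′ to 5′ reads may account for part of it, as the direction followed the end of the tRNA that was read (Fisher's exact p = 0.00482). It is argued against as the cause of all: 8 of the 19 also passed from the last nucleotides alone, 6 lower, among them Val-AAC and Leu-CAA, and 2 higher, and 6 of these 8 did so in the same direction when scaled to library sums. The balance of directions there depends on the scaling: over all anticodons of that part, TMM gave 6 lower and 3 higher and library sums 4 lower and 14 higher. Within the 5′ part alone 7 of 19 tested anticodons passed. Of these, 3 were lower, among them Val-AAC and Val-CAC, and 4 were higher, Gly-GCC, Gly-CCC, Glu-TTC and Lys-TTT. Library sums gave 13 lower and 2 higher in the 5′ part, so directions depend on the scaling there too. A change in tRNA level and a change in fragments that differs between tRNAs stay open and were not tested. In 10 splits of the 6 libraries only the real one, 1 of 10, gave 19 calls, against 0 in the highest other, which is too few splits for a share under 0.05.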

How the results depend on the processing

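The coverage results, the dispersion held at 1 or more, limma at offset 0.01, 1 line per anticodon, pooled reads and all sites 15 nucleotides before the 3′ end were chosen after the data were examined; the other alternatives were fixed before. The cause of the changes below was not tested. For knockdown without AlkB, the count of 0 held in 16 of 16 alternatives, and was 0 to 1 with a library left out (1 without knockdown replicate 2). AlkB in vector stayed at 0 in 11 of 11, and the AlkB-sensitive part at 0 in 7 of 7. Knockdown with AlkB stayed at 0 in 11 of 11 and gave 0 to 2 with a library left out. Among these, 1 line per isodecoder and sites whose base is A moved no tested site and so test nothing. The 1 call of AlkB in knockdown fell to 0 with limma on the fraction, at offsets 0.001, 0.01 and 0.05, with trend and robust, without the replicate block, in the fit over all groups, with dispersion of 1 or more, per anticodon, and with any replicate left out (0 to 0). The IP comparison went from 0 to 4 with limma on the fraction, 3 at offset 0.05, 6 of 7 sites with a mean rate of at least 0.1, 5 with trend and robust, all lower, and to 2 each without the replicate block and over all groups. The 2 input calls fell to 0 at a mean rate of at least 0.1, with trend and robust, with the replicate block and with dispersion of 1 or more, and to 1 per anticodon, and were 3 in the fit over all groups; with a library left out they ranged from 0 to 8.

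The median over all sites ranged from -0.0508 to 0.0166 percentage points with a library left out and turned only without knockdown replicate 2. At other positions it turned to 0.000169 without vector replicate 1 and 0.00939 without knockdown replicate 2, with a lowest value of -0.035 without knockdown replicate 1. The T-loop difference stayed lower in 6 alternatives, from -0.232 to -0.0628, and from -0.172 to -0.0554 with a library left out; the mean over T-loop sites fell by 0.229 percentage points, with an exact permutation p of 0.1. With the replicate block the class medians kept their differences by construction, at -0.131 for T-loop and -0.0282 for all sites.

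Read-through in input stayed higher in 6 alternatives, by 2.91 percentage points with the mix of tRNAs held at the vector mean, by 5.54 without valine tRNAs and up to 6.71, and by 6.19 to 7.12 with a library left out. Its 16 calls became 14 with edgeR, 17 at 10 or 50 reads, 9 by anticodon, 0 with the replicate block and 0 to 13 with a library left out; 49 of 52 tRNAs were higher with the block too. The 19 anticodons became 17 with DESeq2 and with library sums, 18 with the replicate block and 14 to 19 with a library left out. Same-numbered vector and knockdown libraries did not deviate together, and the block leaves fewer degrees of freedom. No site passed the AlkB test in vector, so a test of AlkB-sensitive sites alone gave no value, nor did a mean rate of at least 0.1 in the AlkB-untreated knockdown comparisons. The read minimum limits position 9, where 0 sites could be tested without AlkB.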

Other observations

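The splits of the libraries in the site tests were planned; the other values in this part were chosen after the data were examined.

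The tRNAs differed widely in input read-through of position 58: Tyr-GTA-6-1 had 0.167% in vector and 0.473% in knockdown, against 66.3% and 68.6% for Ala-TGC-3-2 and 67.2% and 67.4% for Ala-CGC-1-1. Phe-GAA had 87% ± 2.4 in vector and 96.2% ± 2.16 in knockdown input (SD, n = 3). Alanine tRNAs as a group had 41.5% ± 1.19 and 45.1% ± 4.83 (SD, n = 3; exact permutation p = 0.3).

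Anticodons of the same amino acid moved apart in knockdown input. Val-TAC was higher, with a log2 fold change of 0.30 (edgeR adjusted p = 0.000701), where Val-AAC and Val-CAC were lower, and Leu-AAG was higher, with 0.42 (edgeR adjusted p = 0.0222), where Leu-CAA and Leu-CAG were lower. Within the last nucleotides alone, Val-TAC had 0.55 (edgeR adjusted p = 1.45e-09) and Val-AAC -0.54 (edgeR adjusted p = 1.51e-20), so that pair parted also where the same part of the tRNA was read.

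In input, 7 of 10 splits of the libraries gave at least the real 2 calls of the site test, with a highest other of 3. Swapping treated and untreated within numbers in knockdown did so in 1 of 4 swaps, where the real count was 1 and the highest other 0. Where the real count was 0, every split reaches it and the splits decide nothing: 10 of 10 with the AlkB-untreated libraries (highest other 3), the AlkB-treated libraries (highest other 2) and the AlkB-sensitive part (highest other 0), and 4 of 4 swaps for AlkB in vector and for IP against input (highest other 0 each). With 10 splits or 4 swaps no share can fall under 0.05.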
